A study of Mus musculus with 10 samples.

How the data were processed

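Cheek skin of C57BL/6 mice aged 6 to 8 weeks was measured by mRNA sequencing, per the labels. The cheek was shaved 3 days earlier, and the right cheek then received an intradermal injection of 5 µL holding either 1 µg of matrix metalloproteinase 9 (MMP9, a secreted gelatinase) or vehicle only. The tissue was collected 4 hours later. The labels number separate mice within each group, 5 given vehicle and 5 given MMP9, so each library is 1 animal. Per the labels' protocols, mRNA was selected with oligo(dT) beads, and single-end reads of 50 bases were made on a DNBSeq instrument, which reads amplified balls of circularised DNA. The composition of the vehicle and the sex of the mice are not given in the sources used here.

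The authors deposited a table of 18994 genes with symbols and Entrez gene identifiers. For each library it holds an estimated read count, which need not be whole (60.8% of the values are not), together with FPKM and TPM values, per the file headers. The FPKM values deposited by the authors are scaled by transcript length and library size, and the deposited TPM values also by their own sum. The authors' columns of group means were not used here. The submitters' processing notes name HISAT as the aligner and GRCm39 as the genome build. The quantification program, the versions, the gene annotation and any read filter are not given in the sources used here. The reference annotation used here is of an earlier build, so no coordinates are printed. Neither strand nor the handling of reads shared by near-identical genes is stated, so counts of paralogs such as hair keratins and keratin-associated proteins, and of genes that overlap or lie antisense to another, are uncertain.

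The deposited estimated counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3: TMM scaling factors, the filterByExpr filter by group, a quasi-likelihood negative binomial fit with treatment as the only term, the F test, and Benjamini-Hochberg adjustment with a threshold of 0.05. The filter kept 15250 genes and left out 3744, and the kept genes held 99.95% of the counts. Levels are given as CPM scaled by the TMM factors, with the SD over the 5 mice of a group. Log2 fold changes are MMP9 over vehicle, with the standard error derived from the F statistic. Intervals are at the 95% level.

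Before the data were examined, 38 gene lists were fixed, covering responses an injected gelatinase or itch could concern, cell types and compartments that cheek skin holds, and handling, time of day and sex. Of their 740 entries, 699 matched the table, 5 of these through synonyms in a RefSeq gene table by Entrez identifier. The 34 lists with at least 5 tested members were tested with camera in limma 3.58.1 on log2 CPM (prior count 2), with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were run beside it. The untested lists were salivary gland (2 tested members), B cell and plasma cell (4), mitochondrially encoded genes (0) and sex-linked genes (1). A list score for a library is the median over members of log2 CPM minus the vehicle mean. The group of 84 ribosomal protein genes was defined from gene symbols after the libraries were examined and is not among the 38 lists.

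The genes named follow a rule set beforehand. Mmp9 is always named. Because fewer than 10 genes passed, the 10 genes with the smallest p are named, as not having passed. For each list described, up to 4 members with the smallest p are named, and which of these 4 are printed was settled after their values were seen. Some genes that the rule names are not reported here. The inner root sheath and shaft keratin genes Krt25, Krt71 and Krt86 lie outside the rule and were chosen after their values were seen.

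The test was checked on simulated counts drawn from the means, dispersions and library sizes of the 15250 tested genes. With 50 genes of at least 1 CPM changed at each size, 24% of 1.5-fold, 64% of 2-fold, 96% of 4-fold and 100% of 8-fold changes were recovered, and 7 of 149 calls were false. These shares depend on how many genes change, since the adjusted threshold is stricter where fewer do. They are therefore not the power of the real comparison. None of the 30 unchanged lists was called (0 of 30), and a list moved by 0.4 on the log2 scale was. The simulated genes vary independently, so this part does not carry the correlation between genes of the real lists (median estimate 0.329) and does not show how often camera with the preset correlation calls unchanged lists.

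Alternatives fixed beforehand were RLE and upper-quartile factors, no filter on low counts, a mean of at least 1 CPM, DESeq2 1.42.0, limma-voom with and without sample quality weights, limma with a trend on log2(FPKM + 1) and log2(FPKM + 0.1), the mouse number as a block, 1 surrogate variable from sva 3.50.0, leaving out muscle, hair, fat and salivary genes, and leaving out each mouse in turn. Limma on log2(TPM + 1), the hair shaft score as a covariate, and fits without vehicle replicate 2 and MMP9 replicate 1, or without these and MMP9 replicate 4, were added after seeing the data. The mouse labels were also regrouped in 100 of the 126 possible splits into equal groups, the real split included, drawn with a fixed seed.

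Total counts were 17121595 to 19443136 per library, with means of 18350000 ± 685400 for vehicle and 18380000 ± 847800 for MMP9 (SD, n = 5 each). The median standard error of a log2 fold change was 0.15, and the median biological coefficient of variation was 18.5%.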

Results

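The mRNA of cheek skin was measured in 10 mice, 5 injected intradermally with MMP9 and 5 with an equal volume of vehicle, with tissue taken 4 hours later. MMP9 is a secreted gelatinase that cleaves denatured collagen and basement membrane collagen. Total estimated counts lay between 17121595 and 19443136 per library. Between 17225 and 17553 of the 18994 listed genes had at least 1 count in a library. By TPM, the most abundant transcript was Krtdap, a gene of differentiating keratinocytes, at 8259 ± 990 TPM in vehicle and 9589 ± 2678 TPM in MMP9 (SD, n = 5). It was followed by Acta1, the skeletal muscle actin, at 8479 ± 2612 and 7480 ± 1778 TPM. Transcripts of muscle as well as of epidermis were thus abundant in both groups. No pair of libraries was a duplicate: chi-square per gene was at least 18.5 between any pair, where sampling noise alone gives about 1.

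The single comparison of the design asks which genes of the cheek skin differ in expression 4 hours after MMP9, and no gene passed the test. Genes of the type I interferon response, T cells and related lymphocytes, dendritic and Langerhans cells and mast cells were on average slightly higher in the MMP9 group. Genes induced by glucocorticoids were on average lower. Genes of the hair shaft, melanocytes and cholesterol synthesis were also lower, but each of these lists lost its call without a single vehicle library, and the hair shaft and cholesterol medians turned sign under an alternative. The list medians lay between -1.23 and 0.39 on the log2 scale, and none of the lists was called when the correlation between genes was estimated from the data. Scores above all vehicle libraries were seen in 4 of 5 MMP9 libraries for interferon and for lymphocyte genes. The same held in 3 of 5 for mast cell and 1 of 5 for dendritic cell genes. For glucocorticoid genes, 2 of 5 MMP9 libraries scored below all vehicle libraries. Of 100 splits of the 10 libraries, 18 called at least as many lists as the real split, so chance is not excluded.

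With edgeR's quasi-likelihood test, 0 of 15250 genes passed at a Benjamini-Hochberg adjusted p of 0.05, 0 higher and 0 lower in MMP9, and the lowest adjusted p was 0.981. At an unadjusted p under 0.05 there were 487 genes, 316 higher and 171 lower, where 762 are expected with no effect. DESeq2, run on all 18994 genes without that filter, called 1 gene and had 620 at an unadjusted p under 0.05. Limma-voom, on the 15250 genes, called 0 and had 462. For 13756 genes (90.2%) the 95% interval of the log2 fold change lay within 1 of 0. Larger changes were therefore excluded, at that level, for most genes taken singly. All 5 MMP9 libraries lay above all 5 vehicle libraries for 65 genes and below them for 21, together 0.564% of the tested genes, where chance gives 0.794%.

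**Figure D1:**
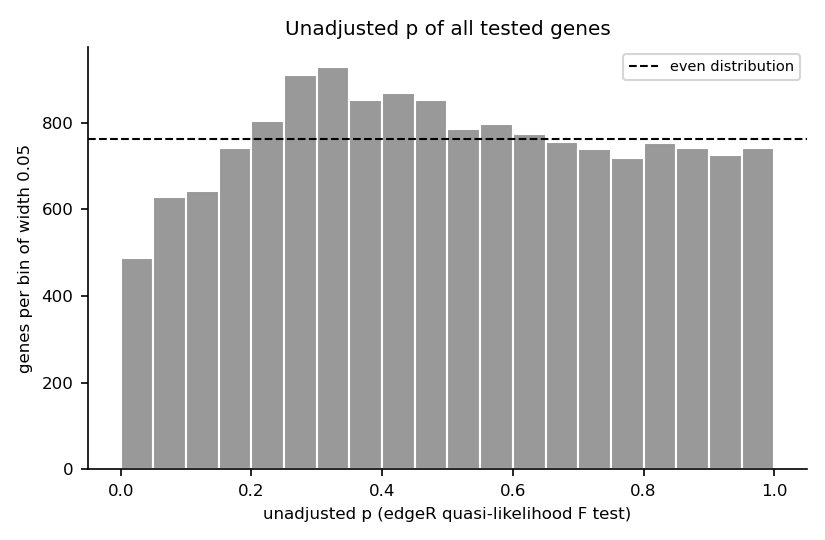
Histogram of the unadjusted p of the 15250 tested genes (x axis, edgeR quasi-likelihood F test) as genes per bin of width 0.05 (y axis), with a dashed line at the 762 genes of an even distribution. The first bin, at p under 0.05, holds 487 genes and lies below the line.

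Transcripts of the endogenous Mmp9 gene (Entrez gene 17395) stood at 21.2 ± 8.02 CPM in vehicle and 22.3 ± 12.3 CPM in MMP9 (SD, n = 5). The log2 fold change was 0.07 with a standard error of 0.37 and an edgeR adjusted p of 0.992, and its 95% interval ran from -0.74 to 0.88. Its sign was not stable, with values from -0.30 to 0.26 over the alternatives. The injected protein is not measured by sequencing.

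None of the 10 genes with the smallest p passed, and each had an edgeR adjusted p of 0.981. For 9 of the 10 the groups did not overlap, which follows in part from their selection by p. The smallest p belonged to Pnliprp2 (Entrez gene 18947), a pancreatic lipase-related gene, with 10.1 ± 2.03 CPM in vehicle and 16.4 ± 1.07 CPM in MMP9 (SD, n = 5). Its log2 fold change was 0.71 with a standard error of 0.14. It was the gene called by DESeq2, with an adjusted p of 0.0384, and over the 26 alternatives its adjusted p ran from 0.0384 to 1. Psmb10 (Entrez gene 19171), an immunoproteasome subunit, had 51.6 ± 4.22 and 70.9 ± 9.46 CPM. Cd247 (Entrez gene 12503), the zeta chain of the T cell receptor complex, had 14.3 ± 1.43 and 19.3 ± 2.59 CPM. C1qtnf2 (Entrez gene 69183) had 9.94 ± 2.75 and 16 ± 1.41 CPM, and Olfml3 (Entrez gene 99543) had 94.9 ± 10.3 and 121 ± 5.13 CPM. Edn3 (Entrez gene 13616), which encodes endothelin 3, had 2.80 ± 0.154 and 4.15 ± 0.661 CPM. The gene models Gm2026 (Entrez gene 100039060) and 6720473M11Rik (Entrez gene 115488623) had log2 fold changes of 0.89 and 0.79, and Plk5 (Entrez gene 216166) of 1.00, the last from 0.62 ± 0.203 to 1.24 ± 0.229 CPM.

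**Figure D2:**
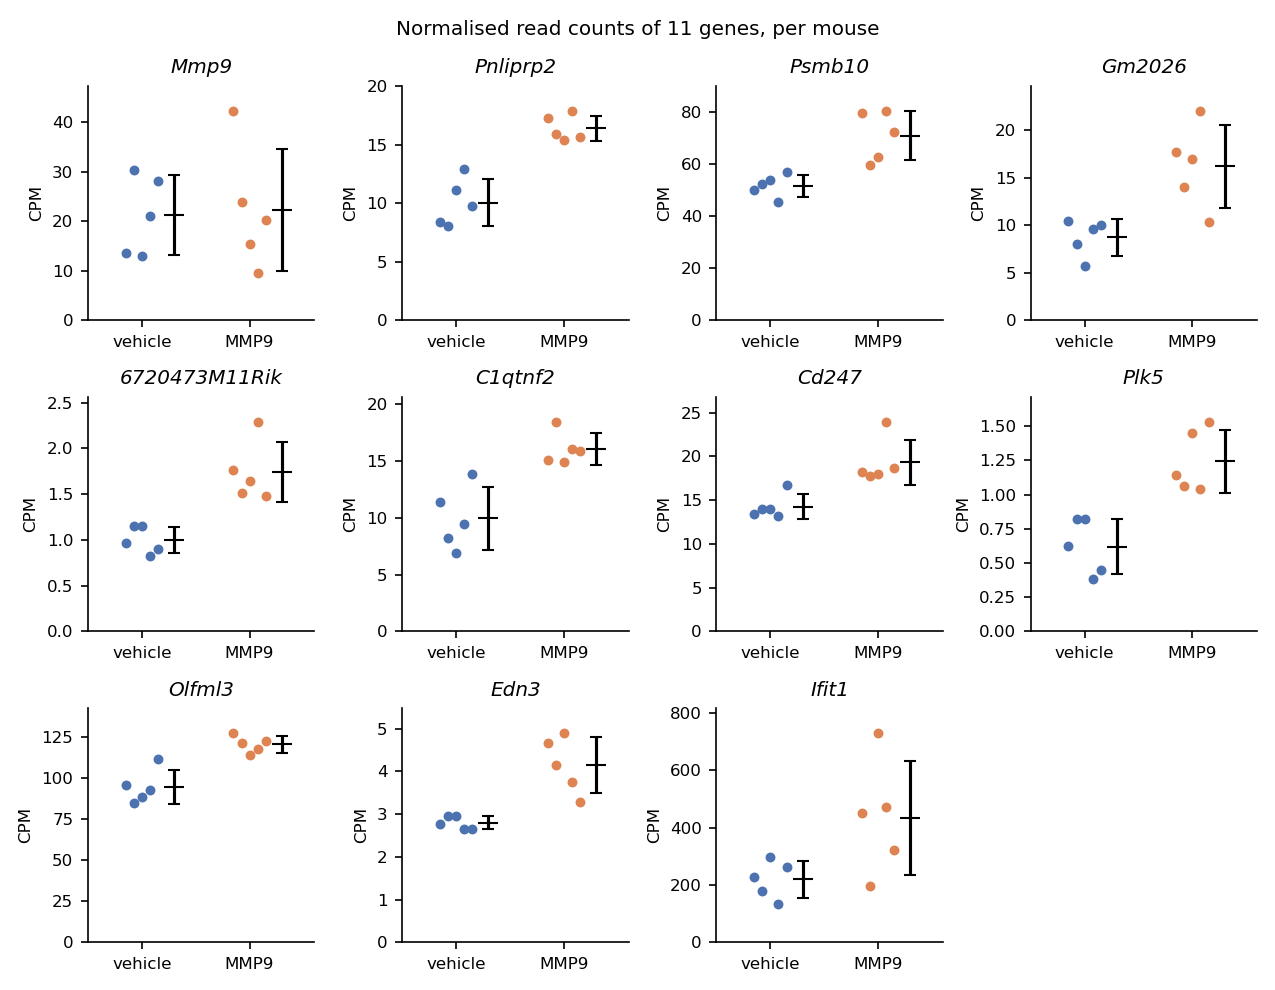
CPM (y axis, from 0) of 11 genes in each mouse given vehicle or MMP9 (x axis); points are single mice, and the bar beside them is the mean with the SD of 5 mice. The panels show Mmp9, 9 of the 10 genes with the smallest p, and Ifit1, and the Mmp9 groups overlap at 21.2 ± 8.02 and 22.3 ± 12.3 CPM.

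Of the 34 tested lists, camera with a preset correlation of 0.01 called 18, 7 toward higher and 11 toward lower values in MMP9, and 16 were not called. The medians of 14 of these 16 changed sign under at least 1 alternative, so their signs carry no direction. With an estimated correlation it called 0 lists, with 3 at an unadjusted p under 0.05 and a lowest adjusted p of 0.278. Fry, which asks whether a list's genes move one way on balance, called 0, with 2 at an unadjusted p under 0.05 and a lowest adjusted p of 0.324. It also called 0 for change in either direction. Over all genes tested, 0 members of any list passed in edgeR. Adjusted over the list alone, 1 member passed, Cd247 in the lymphocyte list, with an edgeR adjusted p of 0.0449. That adjustment takes no account of the 34 lists tested, so 1 such pass can arise by chance.

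Interferon and lymphocyte genes gave the smallest camera p. In the type I interferon list, 16 of 16 members had positive log2 fold changes, with a median of 0.39. Camera gave it an adjusted p of 3.67e-08, against an adjusted p of 0.505 with an estimated correlation. The antiviral gene Ifit1 stood at 220 ± 65.6 CPM in vehicle and 435 ± 199 CPM in MMP9, and Ifit2 at 86.7 ± 19.7 and 140 ± 41.4 CPM. Rsad2 had a log2 fold change of 0.73 and Cmpk2 of 0.56. The list score was above all vehicle libraries in 4 of 5 MMP9 libraries, and it was -0.03 in MMP9 replicate 2. In the T, innate lymphoid and NK cell list, 16 of 18 members were positive, with a median of 0.38 and a camera adjusted p of 2.95e-07, and the list's adjusted p was 0.278 with an estimated correlation. Cd3g, a T cell receptor subunit, had 20.7 ± 2.40 and 28.4 ± 6.93 CPM. The kinase gene Lck and the costimulator gene Icos had log2 fold changes of 0.43 and 0.66. The Cd247 and Cd3g values were highest in MMP9 replicate 4, at 23.9 and 40.5 CPM, a library that also had a high share of ribosomal protein transcripts.

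Dendritic and Langerhans cell genes had positive values in 14 of 15 members, with a median of 0.33 and a camera adjusted p of 1.24e-05, against an adjusted p of 0.47 with an estimated correlation. Cd207, the langerin gene, had 19.9 ± 4.87 and 29.0 ± 9.30 CPM, and Xcr1, a chemokine receptor of cross-presenting dendritic cells, had a log2 fold change of 0.59. Mast cell genes were positive in 12 of 14 members, with a median of 0.33 and a camera adjusted p of 0.000404, and the list's adjusted p was 0.596 with an estimated correlation. Among them were Ms4a2, a subunit of the high-affinity IgE receptor, at 2.56 ± 1.04 and 4.18 ± 0.581 CPM, and the protease gene Mcpt4 at 99.5 ± 51.6 and 140 ± 28.0 CPM. The monocyte and macrophage list was not called (adjusted p 0.525), and its signs differ, with a median of -0.06, a mean of 0.02 and a camera direction toward higher values. It was called toward lower values without vehicle replicate 3 (median -0.22, adjusted p 0.0184) and toward higher values without vehicle replicate 4 (0.07, adjusted p 0.0314) or 5 (0.37, adjusted p 0.000466). Cx3cr1 had a log2 fold change of 0.60 and the scavenger receptor gene Cd163 of -0.71. The neutrophil list was not called either (camera adjusted p 0.975), with a median of 0.06, a mean of -0.08 and a camera direction toward higher values. S100a8 and S100a9, abundant neutrophil alarmins, had log2 fold changes of -1.14 and -0.96 with standard errors of 0.75 and 0.70, which went to -0.06 and -0.16 without vehicle replicate 2, and the formyl peptide receptor gene Fpr1 had -0.98. The neutrophil genes Ly6g, Camp and Ltf had 10, 16 and 12 counts over all 10 libraries and were below the filter.

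Acute inflammatory cytokine and chemokine genes were positive in 18 of 24 members, with a median of 0.24 and a camera adjusted p of 0.0156, and the list's adjusted p was 0.866 with an estimated correlation. The chemokine genes Ccl4, Ccl7 and Ccl2 had log2 fold changes of 0.92, 0.77 and 0.74, with standard errors of 0.52, 0.46 and 0.50. The list score ranged from -0.92 to 1.04 over the libraries, with an SD of 0.716 in vehicle and 0.611 in MMP9. Bacterial-product response genes, a list of genes that endotoxin in a recombinant protein could induce, were not called (camera adjusted p 0.144), with a median of 0.09 and 10 of 16 members positive. Contamination itself was not measured and is not excluded. The list was called toward higher values without vehicle replicate 4, vehicle replicate 5 or MMP9 replicate 2. Cxcl10 had 96.1 ± 35.4 and 176 ± 93.3 CPM, and Il12b, which is barely detected, had 0.395 ± 0.182 and 0.872 ± 0.437 CPM.

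No tested itch gene passed in edgeR. The itch mediator list was not called, with 9 of 18 members positive, a median of -0.004 and a camera adjusted p of 0.614. Postn, which encodes periostin, had 526 ± 61.3 and 669 ± 217 CPM, and the kallikrein gene Klk6 had 152 ± 93.7 and 110 ± 25.8 CPM. The log2 fold change of Klk6 went from -0.48 to -0.05 without vehicle replicate 2, at 307 CPM. The cytokine genes Il4, Il13, Il25 and Il2 had 15, 56, 37 and 16 counts over all 10 libraries, and the neuropeptide genes Tac1 and Calca had 76 and 62, and all were below the filter and were not tested. Il31 was not analysed here. The itch receptor and channel list was not called (camera adjusted p 0.766), with 13 of 27 members positive. Its median was -0.03, its mean 0.01 and its camera direction toward lower values. Il31ra, a subunit of the interleukin 31 receptor, had 38.7 ± 5.34 CPM in vehicle and 28.4 ± 5.03 CPM in MMP9, a log2 fold change of -0.44. Tlr3, Trpv4 and Cysltr2 had log2 fold changes of 0.41, -0.26 and 0.49. The group means of each of these 4 genes differed by more than the SD of either group, which follows in part from their selection by p. Each had an edgeR adjusted p of 0.981.

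The metalloproteinase and fibroblast lists were called toward higher values, but 0 of 5 MMP9 libraries scored above all vehicle libraries in either. The metalloproteinase score was 0.0008 ± 0.388 in vehicle and 0.215 ± 0.125 in MMP9 (SD, n = 5). The fibroblast score was 0.008 ± 0.355 and 0.163 ± 0.0932. The list of matrix metalloproteinases and their inhibitors was positive in 14 of 16 members, with a median of 0.18 and a camera adjusted p of 0.0349, against an adjusted p of 0.739 with an estimated correlation. Mmp12, the macrophage elastase gene, had 10.6 ± 8.56 CPM in vehicle and 71.6 ± 103 CPM in MMP9, a mean set largely by 252 CPM in MMP9 replicate 5. Mmp11 had a log2 fold change of 0.86 with a standard error of 0.43. The list of collagens and laminins was not called (camera adjusted p 0.789), with a median of 0.05 and a mean of 0.04 but a camera direction toward lower values. Its proteoglycan genes Lum and Dcn had log2 fold changes of 0.66 and 0.43, and Col4a1, a basement membrane collagen gene, had -0.30. Fibroblast genes were positive in 14 of 15 members, with a median of 0.16 and a camera adjusted p of 0.00271, and the list's adjusted p was 0.644 with an estimated correlation. Crabp1 had 54.2 ± 13.1 and 76.0 ± 17.3 CPM, and Ly6a had 642 ± 92.2 and 815 ± 187 CPM.

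Hair shaft genes had the largest list median and the largest spread. They were negative in 33 of 34 members, with a median of -1.23 and a camera adjusted p of 0.000538, against an adjusted p of 0.814 with an estimated correlation of 0.773. With 1 surrogate variable the list was called in the other direction (median 0.78, camera adjusted p 0.0468), and without vehicle replicate 3 the median was -0.54 and the list was not called (adjusted p 0.258). The list score was -6.14 in vehicle replicate 2 and -5.92 in MMP9 replicate 1, and it lay between -0.75 and 2.93 in the other 8 libraries. Krt71, an inner root sheath keratin, had 1.37 and 1.71 CPM in these libraries and 67.2 to 1738 CPM in the others. Krt86, a shaft keratin, had 0.0546 and 0.363 CPM, against 58.0 to 505 CPM. Krt25 had 0.109 and 0.311 CPM, against 24.5 to 997 CPM. In vehicle replicate 2, Krt86 and Krt25 lay below 0.164 CPM, the level of 3 counts. The size of scores this low depends in part on the prior count of 2. Among the members with the smallest p, Krtap3-2 had a log2 fold change of -1.24, the hair matrix regulators Foxn1 and Dlx3 had -0.83 and -0.73, and Krt84 had 2.03 through a value of 51.7 CPM in MMP9 replicate 5. Melanocyte genes were negative in 7 of 7 members, with a median of -0.66 and a camera adjusted p of 0.000625, and the list's adjusted p was 0.596 with an estimated correlation. The pigment genes Pmel and Tyrp1 had 8.74 ± 4.30 and 5.53 ± 1.23 CPM, and 15.1 ± 5.29 and 11.2 ± 1.62 CPM. The melanocyte score was lowest in the same libraries as the hair shaft score, at -0.98 in MMP9 replicate 1 and -0.82 in vehicle replicate 2.

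**Figure D3:**
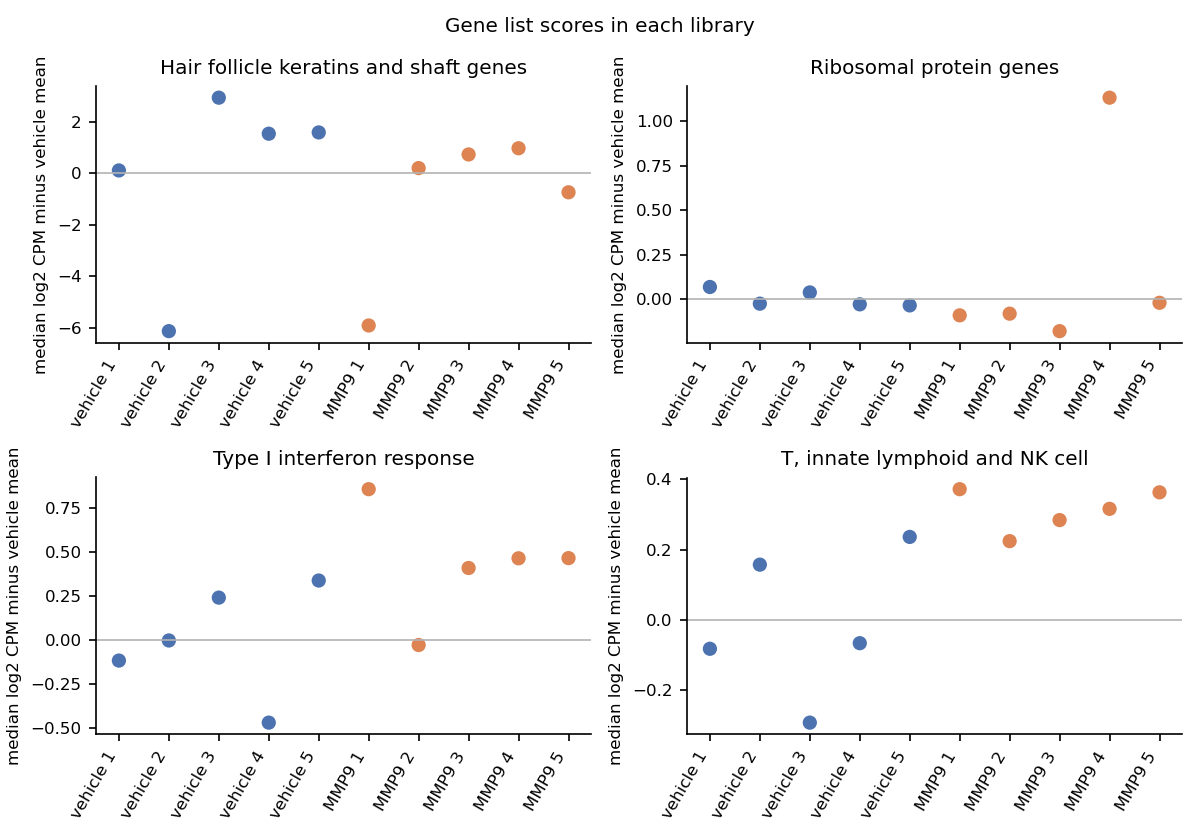
List score of each library (x axis; blue vehicle, orange MMP9) as the median over list members of log2 CPM minus the vehicle mean (y axis), for 4 gene groups. Hair shaft genes stand at -6.14 in vehicle 2 and -5.92 in MMP9 1, and ribosomal protein genes at 1.13 in MMP9 4.

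In the epidermis, terminal differentiation genes were not called (camera adjusted p 0.66), with a median of -0.01. The transglutaminase genes Tgm3 and Tgm1 had log2 fold changes of -1.19 and -0.27, and the keratin gene Krt2 of 0.44. Genes of stressed or wounded keratinocytes were not called (camera adjusted p 0.276), with a median of -0.12 that went to -0.53 without MMP9 replicate 1. Krt6a, a keratin of activated keratinocytes, had 516 ± 150 and 313 ± 123 CPM, the cytokine gene Il20 had 2.29 ± 2.25 and 0.495 ± 0.413 CPM, and the defensin gene Defb14 had 1.30 ± 0.771 and 2.04 ± 0.885 CPM. Tight and adherens junction genes were negative in 20 of 23 members, with a median of -0.07 and a camera adjusted p of 0.0118, against an adjusted p of 0.814 with an estimated correlation. The cadherin genes Cdh3 and Dsg3 had log2 fold changes of -0.36 and -0.31. Sebaceous gland genes were not called (camera adjusted p 0.525), with a median of -0.09. The wax synthase gene Awat2 had 132 ± 27.4 and 204 ± 64.2 CPM, and the fatty acid elongase gene Elovl3 had 276 ± 176 and 158 ± 38.6 CPM.

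Endothelial genes were negative in 14 of 17 members, with a median of -0.12 and a camera adjusted p of 0.00647, and the list's adjusted p was 0.743 with an estimated correlation. Plvap, a protein of fenestrated endothelium, had 187 ± 13.5 and 154 ± 20.0 CPM. Schwann cell and nerve genes were negative in 14 of 16 members, with a median of -0.14 and a camera adjusted p of 0.00206, against an adjusted p of 0.596 with an estimated correlation. The myelin gene Pmp22 had a log2 fold change of -0.24. Skeletal muscle, adipocyte and blood genes were not called, with medians of 0.01, 0.07 and -0.01 and camera adjusted p of 0.975, 0.827 and 0.614. The mean of the blood list was -0.09. Their scores differed between mice of one group by as much as between groups, and the muscle score ran from -0.50 to 0.42. Myh8 had a log2 fold change of 0.94. The adipocyte genes Adipoq and Gpd1 had 0.34 and -0.23, and the erythroid genes Hbb-bs and Slc4a1 had 0.34 and -1.17.

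Glucocorticoid response genes were negative in 11 of 15 members, with a median of -0.33 and a camera adjusted p of 7.28e-07, and the list's adjusted p was 0.338 with an estimated correlation. Zbtb16, a strongly induced glucocorticoid target, had 48.6 ± 27.1 CPM in vehicle and 22.4 ± 1.83 CPM in MMP9. Map3k6 and Pdk4 had log2 fold changes of -0.50 and -0.73. Immediate early genes were negative in 19 of 25 members, with a median of -0.11 and a camera adjusted p of 0.000625, against an adjusted p of 0.596 with an estimated correlation. The matricellular gene Ccn2 had 144 ± 33.6 and 95.7 ± 35.7 CPM, and the phosphatase gene Dusp1 had 125 ± 24.0 and 95.8 ± 18.7 CPM. Heat shock genes were negative in 12 of 13 members, with a median of -0.07 and a camera adjusted p of 0.0458, and the list's adjusted p was 0.814 with an estimated correlation. Hspa1a had 246 ± 254 and 136 ± 63.7 CPM, a difference that rested on vehicle replicate 1, at 686 CPM, without which the log2 fold change was 0.0007.

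Lipid and cholesterol synthesis genes were negative in 18 of 21 members, with a median of -0.15 and a camera adjusted p of 0.000625, against an adjusted p of 0.739 with an estimated correlation. Cell proliferation genes were negative in 20 of 26 members, with a median of -0.27 and a camera adjusted p of 0.0293, and the list's adjusted p was 0.918 with an estimated correlation. The mitotic genes Ube2c and Ccnb1 had log2 fold changes of -0.48 and -0.41, and the replication genes Mcm3 and Pcna of 0.28 and 0.24. Mitogen-activated kinase feedback genes were negative in 12 of 16 members, with a median of -0.13 and a camera adjusted p of 0.00332, against an adjusted p of 0.596 with an estimated correlation. Spred2 and Etv5 had log2 fold changes of -0.26 and -0.28. The transforming growth factor beta, Wnt and oxidative stress lists were not called, with medians of -0.01, -0.06 and -0.02 and camera adjusted p of 0.66, 0.666 and 0.525. The mean of the oxidative stress list was 0.02. Tagln, of the first of these lists, had a log2 fold change of 0.27. The Wnt pathway genes Sfrp2, Dkk3 and Lef1 had 0.64, -0.29 and -0.74, and the oxidative stress genes Gsta3 and Osgin1 had 0.61 and -0.32.

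**Figure D4:**
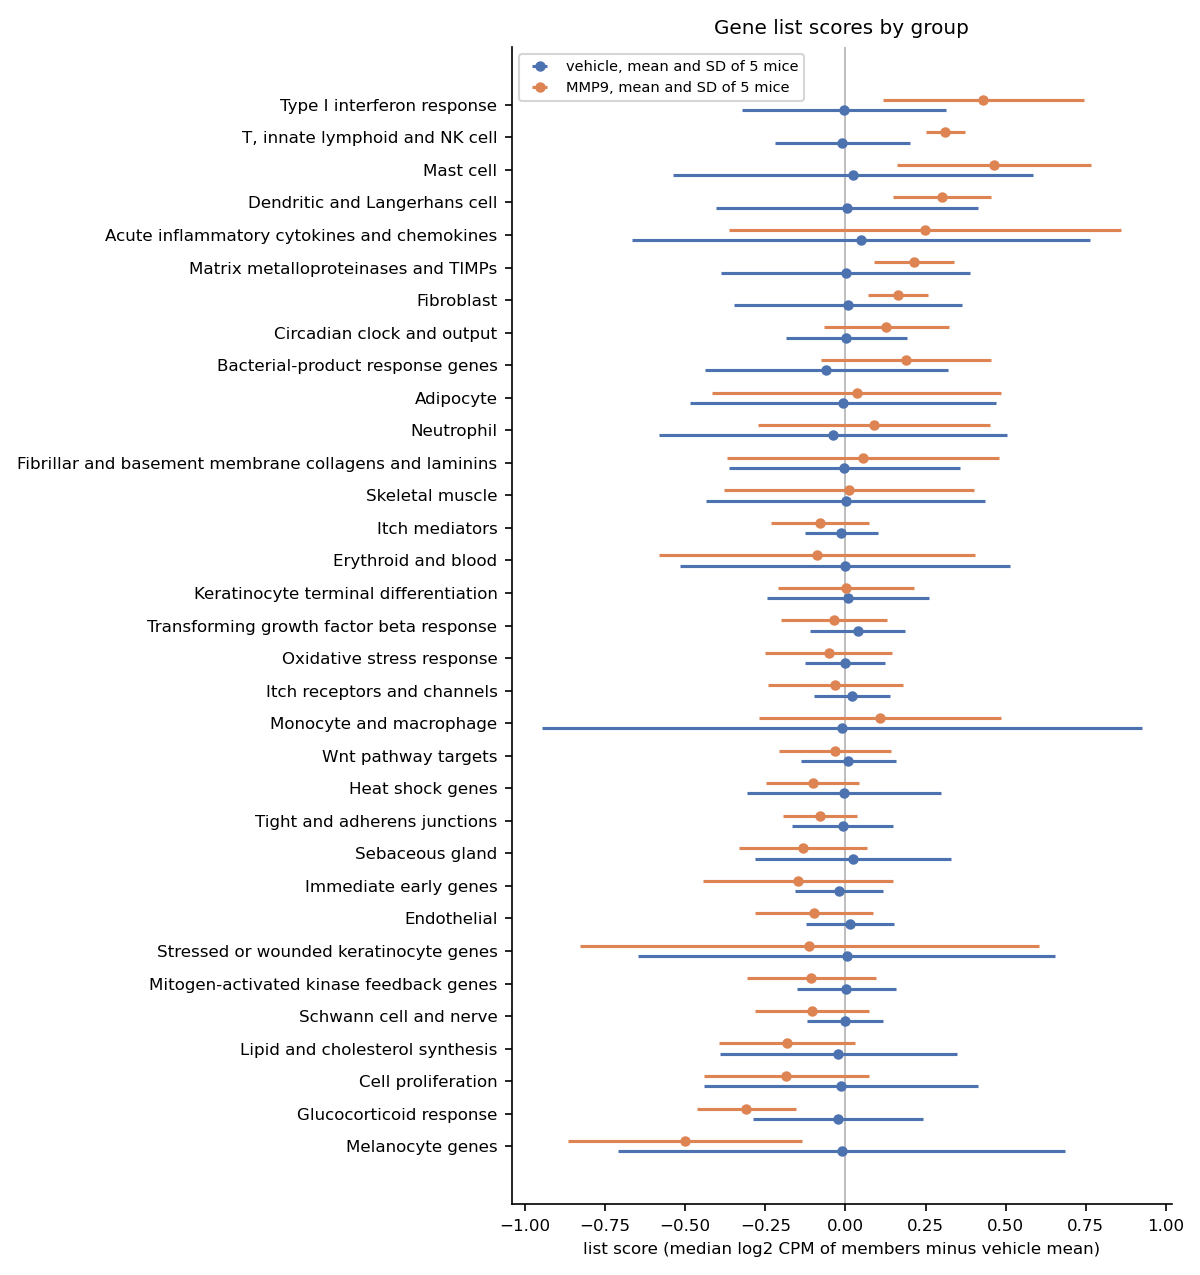
Score of each tested list except the hair shaft list (y axis) as the median log2 CPM of its members minus the vehicle mean (x axis); points and bars are the mean and SD of 5 mice given vehicle (blue) or MMP9 (orange). The type I interferon scores are -0.003 ± 0.318 and 0.431 ± 0.314, and the SD bars of the groups overlap for most lists.

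Many list calls were marginal, and leaving out 1 library ended the call of 13 of the 18 lists. The metalloproteinase, cytokine and proliferation calls each ended under 5 of these fits, so they did not rest on 1 library alone. Leaving out a mouse also lowers the power of the test. The values that follow are camera adjusted p without the library named. The metalloproteinase list had 0.0506 without vehicle replicate 1, 0.339 without vehicle replicate 2, 0.412 without vehicle replicate 3, 0.122 without MMP9 replicate 1 and 0.0851 without MMP9 replicate 5. The cytokine list had 0.0667, 0.547 and 0.0898 without vehicle replicates 1, 2 and 4, and 0.218 and 0.608 without MMP9 replicates 1 and 3. The proliferation list had 0.97 and 0.54 without vehicle replicates 2 and 5, and 0.0995, 0.159 and 0.409 without MMP9 replicates 2, 3 and 4. The junction list had 0.238 and 0.259 without vehicle replicates 2 and 3, and 0.138 and 0.291 without MMP9 replicates 4 and 5. The endothelial list had 0.0597 and 0.0578 without vehicle replicates 1 and 4, and 0.353 and 0.168 without MMP9 replicates 3 and 4. The heat shock list had 0.957 and 0.0753 without vehicle replicates 1 and 4, and 0.315 and 0.425 without MMP9 replicates 2 and 5. The hair shaft list had 0.258 without vehicle replicate 3 and 0.565 without MMP9 replicate 1. Fibroblast genes had 0.0824 and 0.181 without vehicle replicates 2 and 3, and Schwann cell genes had 0.0525 without vehicle replicate 2 and 0.0592 without MMP9 replicate 3. Melanocyte genes had 0.0617 without vehicle replicate 3, cholesterol synthesis genes 0.264 without vehicle replicate 2, immediate early genes 0.101 without MMP9 replicate 4 and kinase feedback genes 0.0656 without MMP9 replicate 2. The interferon, dendritic cell, lymphocyte, mast cell and glucocorticoid lists were called by camera with the preset correlation under each of the 26 alternative fits. With an estimated correlation their camera adjusted p were 0.505, 0.47, 0.278, 0.596 and 0.338, and fry called none of them. Their medians still moved: the interferon median went from 0.39 to 0.18 without vehicle 2, MMP9 1 and MMP9 4, and the lymphocyte median from 0.38 to 0.24 on log2(FPKM + 1) and 0.22 on log2(TPM + 1).

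Other alternatives ended calls as well. With sample quality weights in limma-voom, the metalloproteinase, cytokine, junction, endothelial, Schwann cell and proliferation lists were not called, with camera adjusted p of 0.113, 0.491, 0.262, 0.0617, 0.262 and 0.956, and the camera direction of proliferation genes turned (median -0.05). The proliferation call also ended on log2(FPKM + 1), log2(FPKM + 0.1) and log2(TPM + 1), with camera adjusted p of 0.102, 0.132 and 0.051. The heat shock call ended with 1 surrogate variable (0.175), without the low-count filter (0.0548) and with the hair shaft score as a covariate (0.082). The metalloproteinase call ended with upper-quartile factors (0.0725) and without the low-count filter (0.0599). Without vehicle 2 and MMP9 1, the metalloproteinase, cytokine, proliferation and cholesterol calls ended, with camera adjusted p of 0.448, 0.87, 0.223 and 0.173, and the camera direction of cytokine genes turned (median 0.01). Without MMP9 4 as well, these and the Schwann cell call ended, with 0.221, 0.92, 0.92, 0.821 and 0.0695, and the cholesterol median was 0.01. The same fit gave calls to 2 lists not called, with camera adjusted p of 0.00171 and 0.0287. These were stressed keratinocyte genes, toward lower values (median -0.69), and clock genes, toward higher values (median 0.29).

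The medians of called lists also moved by over 1.5 times without single libraries. Cholesterol synthesis genes went from -0.15 to -0.02 without vehicle replicate 2 and to -0.24 without MMP9 replicate 3. Hair shaft genes went from -1.23 to -0.54 and melanocyte genes from -0.66 to -0.21 without vehicle replicate 3. Dendritic and Langerhans cell genes went from 0.33 to 0.19 without vehicle replicate 3, and mast cell genes from 0.33 to 0.22 without vehicle replicate 3 and to 0.53 without vehicle replicate 4. Fibroblast genes went from 0.16 to 0.09 and 0.06 without vehicle replicates 2 and 3, and proliferation genes from -0.27 to -0.14 without vehicle replicate 2. Cytokine genes, at 0.24, had 0.10, 0.12 and 0.47 without vehicle replicates 2, 4 and 5, and 0.39 and 0.05 without MMP9 replicates 2 and 3. Metalloproteinase genes, at 0.18, had 0.10 and 0.37 without vehicle replicates 3 and 5, and 0.27 without MMP9 replicate 2. Junction genes, at -0.07, had -0.03, -0.13 and -0.12 without vehicle replicates 3, 4 and 5, and -0.13, -0.05 and -0.03 without MMP9 replicates 1, 4 and 5. Endothelial genes, at -0.12, had -0.18 without vehicle replicate 2, and -0.20, -0.07 and -0.05 without MMP9 replicates 1, 3 and 4. Schwann cell genes went from -0.14 to -0.22 without MMP9 replicate 2, and immediate early genes from -0.11 to -0.16 without MMP9 replicate 1 or 3. Kinase feedback genes, at -0.13, had -0.19 and -0.06 without vehicle replicates 2 and 3, and -0.06 and -0.25 without MMP9 replicates 2 and 3. Heat shock genes, at -0.07, had 0.0007 and -0.11 without vehicle replicates 1 and 2, and -0.02, -0.14, -0.12 and -0.03 without MMP9 replicates 2, 3, 4 and 5.

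Leaving out 1 library also gave a call to 9 of the lists not called, the monocyte and macrophage list among them. Toward higher values, the bacterial-product list was called without vehicle replicates 4 and 5 and without MMP9 replicate 2, with camera adjusted p of 0.0066, 0.0111 and 0.0335 and medians of 0.20, 0.18 and 0.15. The skeletal muscle list was called toward higher values without vehicle replicate 4 (adjusted p 0.0422, median 0.10), and the clock list without vehicle replicate 4 (0.0404, median 0.10) or MMP9 replicate 4 (0.0306, median 0.17). Toward lower values, the stressed keratinocyte list was called without vehicle replicates 1 and 4 and without MMP9 replicates 1 and 4, with adjusted p of 0.0408, 0.00532, 0.0216 and 0.0291 and medians of -0.30, -0.29, -0.53 and -0.23. The differentiation list was called without MMP9 replicate 1 (adjusted p 0.0357, median -0.09), the blood list without MMP9 replicate 4 (0.0162, median -0.38) and the oxidative stress list without MMP9 replicate 3 (0.0411, median -0.10), each toward lower values. The adipocyte list was called toward lower values without vehicle replicate 3 (adjusted p 0.0428, median -0.06) and toward higher values without MMP9 replicate 1 (0.0119, median 0.23). It was also called toward higher values without vehicle 2 and MMP9 1 (0.0255, median 0.21). Quality weights gave the blood list a call toward lower values (0.00415, median -0.35). With 1 surrogate variable, the differentiation and stressed keratinocyte lists were called toward lower values (0.0129 and 0.024, medians -0.08 and -0.21).

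Fold changes of other named genes also fell below 50% of their size without a single library. Without vehicle replicate 3, the log2 fold change of Foxn1 went from -0.83 to -0.31, of Dlx3 from -0.73 to -0.30, of Lef1 from -0.74 to -0.33, of Tyrp1 from -0.44 to -0.21 and of Adipoq from 0.34 to 0.16. The keratin genes Krt71 and Krt25 went from -1.30 to -0.54 and from -1.22 to -0.55 without the same library. Elovl3 went from -0.80 to -0.34 without vehicle replicate 2, and Cd163 from -0.71 to -0.34 without vehicle replicate 4. Without MMP9 replicate 4, Hbb-bs turned from 0.34 to -0.32, Pcna went from 0.24 to 0.11 and Adipoq to 0.11. Ccl7 and Ccl2 went from 0.77 to 0.37 and from 0.74 to 0.32 without MMP9 replicate 3, and Mmp11 from 0.86 to 0.43 without MMP9 replicate 1. Without MMP9 replicate 5, Mmp12 went from 2.76 to 1.32 and Krt84 turned from 2.03 to -0.38.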

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

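The tests of MMP9 as the source of the hair shaft pattern, the fit with the hair shaft score as a covariate, and the bound finally used for MMP9 as the source of the ribosomal pattern, were chosen only after the result was seen. The values below were picked out because 1 mouse lay far from the other 4 of its group. Of 262 groups of 5 values examined, 25 had such a mouse, where chance gives about 13. Which genes were examined was settled in part after their values were seen, and the lists of follicle stem cell and hair matrix genes and the ribosomal protein group were written after these patterns were noticed.

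Hair shaft genes stood apart in vehicle replicate 2 and MMP9 replicate 1. In vehicle replicate 2, Krt71, Krt86 and Krt25 had 1.37, 0.0546 and 0.109 CPM, and in MMP9 replicate 1 Krt86 had 0.363 CPM and the hair shaft score was -5.92. Such low values stand for few counts, so the size of the score differences below depends in part on the prior count of 2. Tissue taken without follicles would also lack follicle stem cell and outer root sheath genes, but the median of that list was 0.0612 in the lower of these libraries and 0.114 in the other, relative to the mean of the other 8, with an SD over those of 0.161. Vehicle replicate 2 received no MMP9, and its hair shaft median differed by -7.46 log2 units from that of the other 4 vehicle libraries, so MMP9 is not the source there; for MMP9 replicate 1, at -6.56 from the other 4 MMP9 libraries, an effect of MMP9 cannot be told apart from other sources, since it is a single library. A different stage of the hair cycle may account for the pattern, but it stays open. The hair matrix regulator list had medians of -0.46 and -0.484, neither beyond the bound of -1 set for that stage nor above -0.25. Values as low were seen in vehicle replicate 1, MMP9 replicate 4 and MMP9 replicate 5, at -0.541, -0.493 and -0.672. Matrix regulators such as Foxn1 and Dlx3 are also members of the hair shaft list, so the regulator list is not independent of the pattern.

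Ribosomal protein genes stood apart in MMP9 replicate 4, where they held 13.2% of the counts, against 6.74% to 7.32% in the other MMP9 libraries, its TMM factor was 0.843, and its ribosomal score was 1.13. The median deviation of 82 ribosomal protein genes from the other 9 libraries was 1.16 on the log2 scale, and after a smooth fit on GC content over other genes 1.15 was left, which argues against GC content. An effect of MMP9 shared by the group would need the other 4 MMP9 libraries above the highest vehicle score of 0.0694. Their median was -0.0848 (SD 0.0656). The bound set beforehand for arguing against such an effect, a median within the vehicle range of -0.0338 to 0.0694, was missed on the low side. That a value this far below the highest vehicle library argues against a shared effect was decided after the value was seen. An effect of MMP9 in MMP9 replicate 4 alone cannot be told apart from other sources, since it is a single library. Transcript length may account for most of the pattern, since a smooth fit on effective length over other genes left 0.341; other genes with an effective length under 500 bases had a median deviation of 1.08 and those above 4000 bases of -0.355, though what made short transcripts more frequent in this library, degradation or handling, was not tested.

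The lists called by camera with a preset correlation could come from the way mice happened to be grouped. Of 100 splits of the 10 libraries, 18 called at least as many lists as the real 18, the other splits called a median of 14, and the highest other split called 23, so chance is not excluded. Without MMP9 replicate 4, 14 of the lists stayed called, so the calls of these did not need that library. With the hair shaft score as a covariate 17 stayed called, but this does not decide about the hair cycle. That score was lowest in vehicle replicate 2 and MMP9 replicate 1, which lie in different groups, and whether it follows the hair cycle stays open. The other splits called at least 5 lists each, so staying called does not tie a list to treatment. For genes the splits decide nothing, since each of the 100 splits calls at least the real count of 0 (100 of 100); the highest other split called 14. At an unadjusted p under 0.05 the real split had 487 genes, against a median of 596 in the others and a highest of 2366, several times the real count, which points to structure among the libraries other than treatment.

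Other single values are given without explanation. Cd247 stood at 16.7 CPM in vehicle replicate 5, above 13.2 to 14 CPM in the others, and at 23.9 CPM in MMP9 replicate 4, above 17.8 to 18.6. MMP9 replicate 4 also had 40.5 CPM of Cd3g, 1143 CPM of Ly6a and a low 284 CPM of Col4a1. Short transcripts were more frequent in this library, and whether that bears on these values was not tested. Il12b was low in MMP9 replicate 3, at 0.15 CPM. Il31ra was low in vehicle replicate 5, at 29.6 CPM, where Awat2 was high, at 181 CPM. Trpv4 was high in vehicle replicate 3, at 25.2 CPM, and Bhlhe41 in vehicle replicate 4, at 44.5 CPM. Krt84 had 1.31 CPM in vehicle replicate 2 and 51.7 CPM in MMP9 replicate 5. Slc4a1 had 0.109 CPM in vehicle replicate 2, below 0.908 to 1.76 CPM in the others, and 0 CPM in MMP9 replicate 1, where a count of 0 allows up to 0.155 CPM for counting error only. Pmp22 was high in MMP9 replicate 2, at 260 CPM, where the neutrophil score was low, at -0.54. The adipocyte score was low in MMP9 replicate 1, at -0.736.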

How the results depend on the processing

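The fits with log2(TPM + 1), with the hair shaft score and without more than 1 library were chosen after seeing the data. The count of 0 changed genes held under 25 of 26 settings, the exception being DESeq2 with 1 gene, higher in MMP9. Genes at an unadjusted p under 0.05 numbered 191 to 742, over settings that tested between 13429 and 18994 genes. Leaving out each mouse in turn gave 0 genes each time, 0 higher and 0 lower. Camera called 18 lists, 0 with an estimated correlation and 0 with fry; leaving out each mouse gave 11 (without vehicle replicate 2) to 20 lists, and other settings 13 to 19. Mouse numbers were not taken as pairs, since the right cheek was injected in both groups, so a shared number was read as separate animals. The correlations of same-numbered deviations ran from -0.242 to 0.455, with 3 of 5 over 0.1, and 1 number of 5 matched best with its own. These values alone do not decide about pairing. With the mouse number as a replicate block, 0 genes and 18 lists were called. Of 3800 values of the 148 named genes under the alternatives, 3779 kept their sign. Of 467 values of called lists, 464 kept their sign and 406 their call and direction. Among the 16 lists not called, whose medians lie near 0, 14 changed sign under at least 1 alternative, in 96 of 414 values. Medians that changed sign with a call in at least 1 of the fits compared were those of hair shaft genes (0.78 with 1 surrogate variable), heat shock genes (0.000663 without vehicle replicate 1, with -0.137 to 0.000663 over single mice left out), adipocyte genes (-0.0646 without vehicle replicate 3, and from -0.0984 without MMP9 replicate 4, not called, to 0.23 without MMP9 replicate 1), monocyte genes (0.07 and 0.37 without vehicle replicates 4 and 5) and cholesterol synthesis genes (0.0119 without vehicle 2, MMP9 1 and MMP9 4); for those with fewer mice the change follows from the samples left out, and for the surrogate variable the cause was not tested. In simulated data at this depth and size, with 50 genes changed at each of 1.5-, 2-, 4- and 8-fold, 64% of 2-fold changes were found. Smaller differences can thus be missed, and where fewer genes change the adjusted threshold is stricter, so larger ones can be missed as well.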

Other observations

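The list of clock genes was fixed before the data were examined, and the test of transcript length in every library was chosen only after the result for MMP9 replicate 4 was seen.

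The circadian clock list was not called by camera (adjusted p 0.28, and 0.918 with an estimated correlation), with a median of 0.11 and 11 of 17 members positive. Camera looks for a shared direction, so members that move opposite ways can cancel in it and in the median. Fry's test for change in either direction gave its lowest p here, 0.00442, but the adjusted p over the lists was 0.14. Per3, a repressor arm gene, had 27.1 ± 6.97 CPM in vehicle and 40.3 ± 10.1 CPM in MMP9, Bhlhe41 had 38.2 ± 3.58 and 49.5 ± 8.12 CPM, and Cry1 had 16.6 ± 3.43 and 22.3 ± 3.99 CPM (SD, n = 5). Arntl, which encodes the activator BMAL1, had 19.5 ± 1.22 and 15.7 ± 2.43 CPM. None of these passed in edgeR, over all genes or adjusted over the list alone (0 of 17, lowest adjusted p 0.0766). The hour of injection of each mouse is not given in the sources used here.

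Across genes other than ribosomal protein genes, which are not independent replicates, the rank correlation between effective length and a library's deviation from the other 9 was -0.669 in MMP9 replicate 4. With that library left out of the reference it was 0.305 in MMP9 replicate 1, and the other 8 libraries lay between -0.0932 and -0.00337.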
